A study of Mus musculus with 2 samples.

How the data were processed

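Single-cell RNA libraries were made from cells of the mouse vitreous after zymosan, a yeast cell wall preparation, had been injected into the eye. Per the labels' protocols, vitreous fluid and a rinse of the retina were collected from C57BL/6 mice, and cells were purified with Ly6G magnetic beads before droplet capture with the 10x Chromium 3' kit. There were 2 libraries, 1 from mice given normal serum (NRS) and 1 from mice given antiserum to the chemokine receptor CXCR2 (aCXCR2). Groups were taken from the source labels.

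The deposited matrices held whole-number UMI counts per gene and barcode, with no normalization per the file headers. The submitters' processing notes name Cell Ranger and Seurat without versions, and the matrix headers give software version 3.0.0. The same notes list a human genome build, whereas the feature tables held mouse Ensembl gene IDs. Of 31053 gene IDs, 30934 (99.62%) were in the GENCODE annotation used here for gene positions. The authors' mouse build is not given in the sources used here, so positions are those of that annotation and not of the deposited files.

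Barcodes with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept. Scrublet in scanpy 1.11.5, run per library, called 0 of 5655 cells in the NRS library and 4 of 4826 in the aCXCR2 library as doublets. At that rate the doublet caller has not worked, and doublets must be taken to remain among the cells. An alternative removed the 256 and 186 highest doublet scores, the numbers expected from the loading. Both libraries were clustered together, using 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method (leidenalg 0.10.2) at resolution 1. No correction for library was made.

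Clusters were named from marker lists fixed before the data were examined. The scoring rule was set after the data were seen. Its prior was raised from 10 to 100 CPM because, with the lower value, a cluster that was neutrophil-like in some settings took a photoreceptor name in another. Results with the lower prior are among the alternatives. A cluster stayed unnamed when its 10 leading genes held more markers of another class than its own, when markers of 2 classes scored at least 0.5, or when it had under 20 cells. Of 29 clusters, 10 were neutrophil-like and 8 stayed unnamed. Clusters whose best-scoring class was monocyte or macrophage and that held at least 20 cells are called macrophage-scoring, whether or not they met the naming rule otherwise. They are clusters 5, 7, 12, 14, 17 and 19, of which 5, 12 and 14 are unnamed.

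Counts were summed per library and class and divided by total UMIs to give CPM. Ratios are aCXCR2 over NRS. With 1 library per group there is no replicate check, no test was made, and no p-value is given. The 95% intervals are exact Poisson intervals for CPM, exact Clopper-Pearson intervals for shares, and exact conditional intervals for ratios. They cover counting error only. A share of 0 allows up to 3 counts of the total. Genes at least 2-fold apart were counted among those with at least 50 CPM in 1 library. For 24 gene lists fixed beforehand, the median log2 ratio of members with at least 10 CPM in 1 library was set among 10000 random lists matched on mean CPM in 20 bins. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs.

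The named genes were fixed by rule. In neutrophil-like cells they are the 12 largest and 12 smallest log2 ratios among genes with at least 50 CPM in 1 library, leaving out Gm and Rik models, mitochondrial genes, and genes over 5 times higher outside the class. In all cells they are the 5 largest and 5 smallest. Up to 4 members were taken from each list with a median beyond 0.3 or a percentile under 2.5 or over 97.5. Ly6g, Cxcr2, Cd101, Cd14, Arg1, Mrc1, Il4ra, Chil3, Igf1 and Mki67 were always included, with markers of named classes. The text gives part of the genes the rule takes, and some are not reported here.

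The ratio step was tested on simulated counts drawn at the real means, with 200 genes changed. For the neutrophil-like comparison, run on 2682 genes, 66 of 66 genes changed 3-fold and 63 of 63 changed 6-fold passed the 2-fold rule, as did 0 of 71 changed 1.5-fold. For the all-cell comparison, run on 2964 genes, these were 66 of 66, 63 of 63 and 0 of 70. The intervals held the true ratio for 94.9% and 94.8% of unchanged genes. These simulations contain no variation between animals. Their ratios were scaled by the totals used to draw the counts. They therefore check the arithmetic and the counting intervals, and do not test the choice of scaling.

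Alternatives changed the cell filter, doublet treatment, clustering, scaling, weighting of cells, CPM minimum, thinning depth and list summary. TMM factors came from edgeR 4.0.16 in R 4.3.3. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.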

Results

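Gene expression was measured in single cells recovered from the vitreous of zymosan-injected eyes, to compare cells from mice given antiserum to CXCR2 with cells from mice given normal serum. Each group was 1 library. The NRS library held 7314 barcodes and 61386486 UMIs, of which 5655 cells were kept with a median of 4759 UMIs. The aCXCR2 library held 5551 barcodes and 85748842 UMIs, of which 4822 cells were kept with a median of 10360.5 UMIs. The cell filter removed 22.7% of NRS barcodes and 13.1% of aCXCR2 barcodes. No value below has a replicate, and intervals cover counting error only.

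Neutrophil-like cells made up about the same part of both libraries in the main clustering, while photoreceptor-like cells were more frequent in NRS and the unnamed clusters 5, 12 and 14 in aCXCR2. Neutrophil-like cells were 51.9% of NRS cells (95% interval 50.6 to 53.2%) and 53.3% of aCXCR2 cells (51.8 to 54.7%). The NRS share depended on whether the unnamed cluster 4 was counted. That cluster, led by Siglecf and best matched to neutrophils, held 11.8% of NRS and 1.97% of aCXCR2 cells, and adding it gave 63.7% and 55.2%. The shares were 64.1% and 55.2% at resolution 0.5, 68.5% and 58.8% with the strict filter, and 30.9% and 51.8% without cluster 1. Near-equal shares are therefore a trait of the main clustering, and no order of the libraries is claimed. Unnamed cluster 15, with markers of neutrophils and rods, held 5.89% of NRS and 1.14% of aCXCR2 cells. Clusters that met the naming rule as macrophage-like held 7.83% of NRS (7.15 to 8.57%) and 9.46% of aCXCR2 cells (8.65 to 10.3%). Clusters 5, 12 and 14 scored highest for macrophages but stayed unnamed, as their leading genes held more markers of another class. They held 0.601% and 12.8% (cluster 5), 1.98% and 6.57% (cluster 12) and 0.371% and 7.69% (cluster 14) of cells. Named and unnamed, these macrophage-scoring clusters summed to 10.8% and 36.6%, although both libraries had been enriched with Ly6G beads. Photoreceptor-like cells were 15.8% of NRS and 5.85% of aCXCR2 cells, and the rod transducin gene Gnat1 stood at 3380 and 1928 CPM in them. Lens cells, with Crybb2 at 4900 CPM in NRS, were 1.57% and 0.145%. The bead enrichment and the cell filter can set all of these shares.

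**Figure D1:**
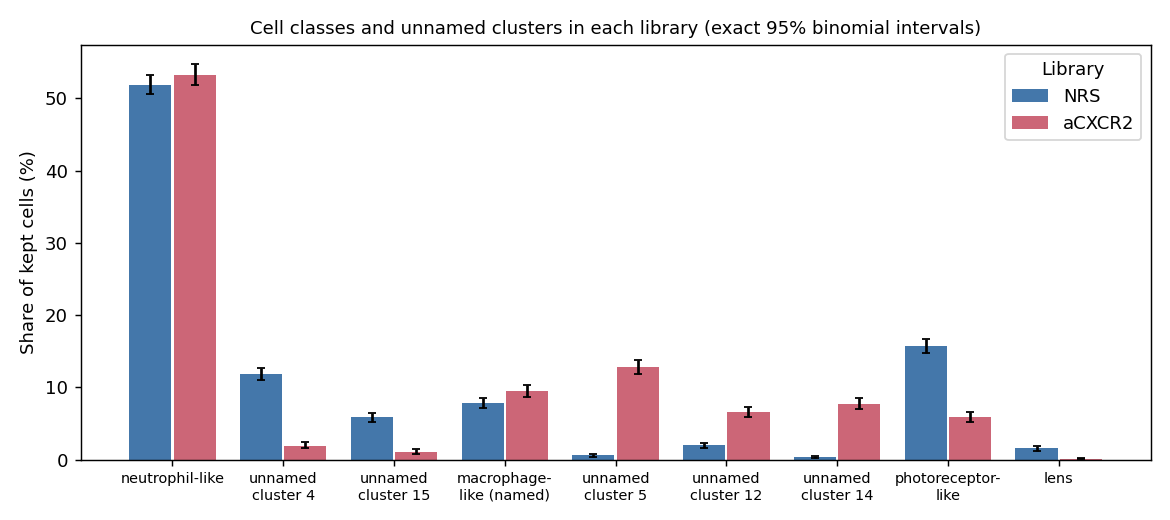
Share of kept cells (percent, vertical axis) in each class and in unnamed clusters for the NRS and aCXCR2 libraries, with exact 95% binomial intervals as error bars. Named macrophage-like clusters hold 7.83% of NRS and 9.46% of aCXCR2 cells, unnamed cluster 5 holds 0.601% and 12.8%, and unnamed cluster 4 is 11.8% of NRS.

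In neutrophil-like cells, genes of neutrophil granules and of the mature neutrophil surface had higher CPM in the aCXCR2 library. Ly6g, the surface antigen used for enrichment, stood at 13.9 CPM in NRS and 121 CPM in aCXCR2 (log2 ratio 3.12, interval 2.92 to 3.34). Ngp, a granule protein gene, was 35.9-fold higher (log2 5.17), Retnlg 23.3-fold (log2 4.54) and Cd177 8.13-fold (log2 3.02). Lipg, an endothelial lipase gene, had the largest ratio (log2 5.99), followed among the 12 largest by Ngp, Saa1 (5.13), the haemoglobin gene Hbb-bt (5.05), Retnlg, BC100530 (3.86), Car4 (3.67), the stefin genes Stfa2 (3.62), Stfa3 (3.61) and Stfa1 (3.22), Ifitm1 (3.29) and Ly6g. Hbb-bt was also in the erythroid marker list, and free RNA was not tested for it. The rule on genes over 5 times higher outside the class would not remove RNA spread evenly over all cells. Cxcr2 itself was 419 CPM in NRS and 747 CPM in aCXCR2 (log2 0.83), a level of transcript that does not report receptor blockade. Ly6g (ENSMUSG00000022582) lies on chromosome 15 at 75155240 to 75159126, Cxcr2 (ENSMUSG00000026180) on chromosome 1 at 74153989 to 74161246, and Arg1 (ENSMUSG00000019987) on chromosome 10 at 24915221 to 24927484 in the annotation used here.

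Genes with lower CPM in aCXCR2 neutrophil-like cells included Bhlhe41 (log2 -3.68), the stress-induced cytokine gene Gdf15 (-3.29), the cathepsin gene Ctsk (-3.21), Osbpl3 (-3.02) and Gpnmb (-2.49), with the chemokine genes Ccl9 (-2.67) and Cxcl1 (-2.35). Tnni2 (-2.58), Nceh1 (-2.55), Stx3 (-2.45), Eef1e1 (-2.40) and Gnl3 (-2.38) completed the 12. The granule gene Ltf went against its list, at 183 CPM in NRS and 40.1 CPM in aCXCR2. Of genes at least 2-fold apart, 14 were over 5 times higher outside the class and were kept apart as possible free RNA. They included rod genes such as Gnat1, at 93.6 CPM in NRS and 7.63 CPM in aCXCR2 neutrophil-like cells.

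Of 3162 genes with at least 50 CPM in 1 library, 131 were at least 2-fold higher and 614 at least 2-fold lower in aCXCR2. This balance depended on the scaling. The median gene lay at -0.48 on the log2 scale when counts were divided by total UMIs, and S100a8 alone went from 17270 to 77045 CPM. With TMM factors the median moved up by 0.69 and the numbers were 503 higher and 100 lower, and with median of ratios factors they were 486 and 102. No statement is therefore made that more genes were lower than higher. All of the 24 genes with the largest and smallest ratios have log2 ratios beyond that shift. Different clusters held most of the class in the 2 libraries, clusters 1, 2, 9 and 11 in NRS and clusters 3, 6, 10 and 13 in aCXCR2, and cluster 1, with the weakest neutrophil score (0.2, next class 0.13), held 40.5% of the class in NRS and 2.69% in aCXCR2. Without cluster 1 the numbers were 61 higher and 171 lower. Ctsk, Tnni2, Gdf15 and Ltf were among the 10 leading genes of cluster 1. Lipg and Ifitm1 were among those of cluster 6, and Ngp, Retnlg, Ly6g and Stfa1 among those of cluster 13. Their ratios therefore do not tell a change within cells from a change in the clusters that held the class. When cluster 1 was left out, 2 values of named genes turned sign.

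Gene lists set these differences against random lists of matched expression, whose medians lay between -0.80 and -0.21. Of 11 specific granule genes measured, 9 were over 1.5-fold higher and 2 lower in aCXCR2 (median log2 1.04, above 99.99% of random lists, and 0.87 without cluster 1). Of 8 gelatinase granule genes, 6 were higher and 0 lower, with a median of 1.03 (0.53 without cluster 1), Retnlg and Mmp8 (log2 2.06) leading. Of 11 mature surface genes, 9 were higher and 1 lower (median 0.89, and 0.26 without cluster 1). The surface genes Csf3r, Cxcr2, Ly6g and Il1r2 and the gelatinase genes Retnlg and Mmp9 were also markers in the neutrophil score. Cluster 1 had the lowest such score, so the falls of the surface and gelatinase medians without it are partly built in. Interferon-stimulated genes had 6 of 13 members higher and 2 lower (median 0.58), but their median was -0.027 without cluster 1. Gbp2 (1.99) and Ifitm3 (1.88) were higher and Ifit3 (-1.24) lower, but Ifit3 was at 0.43 with libraries clustered separately. All 9 heat shock genes were over 1.5-fold lower (median -1.60, below all 10000 random lists, and -1.23 without cluster 1), among them Hspa1a (-2.25). Cluster 24, led by the heat shock genes Hspa1b, Hspa1a and Hsph1, held 52 NRS and 5 aCXCR2 cells of the class. How much of the difference it carried was not measured. Of 14 oxidative phosphorylation genes 12 were lower (median -0.89), and of 11 scavenger and lipid handling genes 7 were lower and 0 higher (median -0.88). These counts of lower members rest on scaling by total UMIs, and with TMM factors the medians of these 3 lists were -0.92, -0.21 and -0.19.

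Lists tied to activation were mixed when scaled by total UMIs, and TMM factors raised every list median by 0.69. Of 8 measured alternative activation genes, 4 were higher and 1 lower. Their median was 0.47, with 0.056 without cluster 1 and 1.15 with TMM factors. Il10 (1.94), Il4ra (1.35), Arg1 (1.18) and Cd14 (0.67) were higher. Of these, Arg1 was seen in a share of cells within the interval for photoreceptor-like cells in both libraries. Of 15 classical activation genes, 6 were higher and 2 lower (median 0.34), with Nos2 (1.40) and Il1b (1.01) higher and Tnf (-1.15) lower. The classical median was -0.072 without cluster 1 and 1.02 with TMM factors. Of 24 neurotrophic and growth factor genes only 5 reached 10 CPM, of which 0 were higher and 2 lower, Inhba (-1.78) and Vegfa (-1.40), and the list median turned positive with TMM factors (0.15). MHC class II genes had a median of 1.60 over 4 members (1.26 without cluster 1), with a summed level of only 97.1 CPM in NRS and 143 CPM in aCXCR2. In photoreceptor-like cells the same 4 genes summed to 15.3 CPM (12.9 to 18.0) and 115 CPM (99.5 to 131). In aCXCR2 neutrophil-like cells H2-Aa, H2-Ab1 and H2-Eb1 stood at 17.5, 24.7 and 12.5 CPM. That is no higher than the photoreceptor-like intervals allow (up to 34.4, 38.8 and 18.3 CPM). Cd74, most of the sum, lay above them, at 88.0 CPM (84.2 to 91.9) against 46.8 CPM (37.4 to 57.9) in aCXCR2. In NRS Cd74 was at 79.9 CPM (75.4 to 84.6) against 8.47 CPM (6.73 to 10.5). Clusters 5 and 14, where the 4 genes summed to 11918 and 12679 CPM in aCXCR2, held larger shares of cells in that library. Medians of the other lists were 0.31 for trafficking receptors (-0.14 without cluster 1), 0.30 for matrix remodelling (-0.0011 without cluster 1 and -0.31 as a sum of UMIs), 0.24 for NADPH oxidase, 0.20 for immediate early, 0.12 for chemokine ligand and 0.10 for zymosan recognition genes, of which the last 3 were -0.24, -0.22 and -0.055 without cluster 1. They were -0.21 for apoptosis regulators, -0.26 for glycolysis and -0.39 for hypoxia response (0.47, 0.43 and 0.30 with TMM factors), and -0.73 for neutrophil progenitor and -0.75 for unfolded protein response genes (-0.041 and -0.062 with TMM factors). The median was -1.90 for proliferation genes, of which 4 were measured, but their summed level was higher in aCXCR2, at 485 and 621 CPM (log2 0.36). Only 2 azurophil granule genes were measured, too few for a median.

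**Figure D2:**
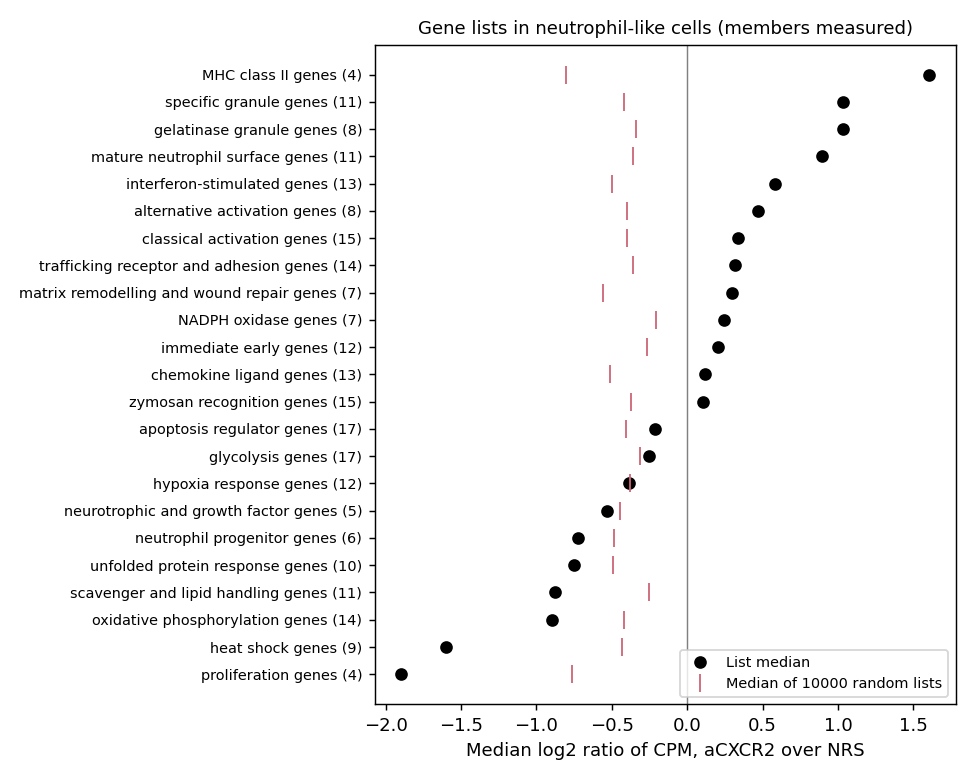
Median log2 ratio of CPM, aCXCR2 over NRS, for each gene list in neutrophil-like cells (points), beside the median of 10000 random lists matched on expression (red ticks). Mature neutrophil surface genes lie at 0.89 and heat shock genes at -1.60.

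Equal-depth shares were higher in aCXCR2 for Cxcr2, Cd14, Il4ra and Ly6g, and placed Arg1, Mrc1 and Igf1 at the level of background. With every cell thinned to 1000 UMIs, 111 NRS and 38 aCXCR2 neutrophil-like cells were left out as shallower. Median depths before thinning were 4601 and 7712.5 UMIs in neutrophil-like cells and 4108 and 4862.5 in photoreceptor-like cells, which should lack these genes. Cxcr2 was seen in 22.6% of NRS and 42.3% of aCXCR2 neutrophil-like cells, against 0.882% and 1.32% of photoreceptor-like cells. Cd14 was seen in 41.5% and 63.0%, against 4.79% and 7.89%. Il4ra was seen in 11.1% and 23.1%, against 1.01% and 1.32%. Ly6g was seen in 1.13% and 7.87%, against 0.126% and 0.439%. Cluster 1 held 40.5% of the neutrophil-like class in NRS and 2.69% in aCXCR2. Shares over the whole class therefore do not tell a change within cells from a change in the clusters that held it. Cd101 was seen in 2.06% and 5.45%, against 0.252% and 0.439%, but this gap depended on the draw and the depth. The shares expected over all draws were 2.91% and 4.82%, those at 500 UMIs were 1.70% (1.27 to 2.24%) and 2.14% (1.62 to 2.78%), and those with cluster 4 added were 3.71% and 4.74%. The proliferation gene Mki67 was seen in 1.24% and 0.474%, against 0 of the photoreceptor-like cells, which allows up to 0.378% and 1.32%. The limit in aCXCR2 comes from only 228 cells, so it cannot tell that share from background. Over all UMIs Mki67 in aCXCR2 stood at 3.99 CPM (3.22 to 4.89) in neutrophil-like and 1.10 CPM (0.133 to 3.98, from 2 UMIs) in photoreceptor-like cells, which overlap. Chil3 was seen in 1.03% and 1.42%, against 0% and 0.439% (0.011 to 2.42%, from 1 cell). Over all UMIs Chil3 stood at 12.5 CPM (10.7 to 14.4) in NRS and 25.6 CPM (23.6 to 27.7) in aCXCR2 neutrophil-like cells, above the 0.837 CPM (0.361 to 1.65) and 1.10 CPM (0.133 to 3.98) of photoreceptor-like cells. The gap between libraries depended on the cells counted. Unnamed cluster 4 held 254 Chil3 UMIs in NRS (87.6 CPM), beside 183 in the NRS neutrophil-like class, and 9 in aCXCR2 (18.7 CPM). Without the highest doublet scores the log2 ratio of Chil3 was -9.40e-05.

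Arg1, an enzyme gene of alternative activation, was seen in 3.01% of NRS and 6.40% of aCXCR2 neutrophil-like cells, against 2.90% (1.85 to 4.31%) and 7.89% (4.75 to 12.2%) of photoreceptor-like cells. Mrc1 was seen in 0.248% and 0.474%, against 0.378% and 0.877%. Both shares lay within the interval of the background. Over all UMIs Arg1 in aCXCR2 stood at 72.1 CPM (68.7 to 75.7) in neutrophil-like and 61.1 CPM (50.3 to 73.6) in photoreceptor-like cells, but in NRS at 31.8 CPM (29.0 to 34.8) and 18.5 CPM (15.9 to 21.5), which do not overlap. The macrophage genes Apoe (462 and 279 CPM) and C1qa (14.2 and 8.37 CPM) differed likewise between these classes in NRS. In macrophage-scoring clusters Arg1 was seen in 58.4% and 75.6% of cells, and those clusters held 94.2% and 98.5% of all Arg1 UMIs. They held Cxcr2 in 0.669% and 1.20% of cells and Ly6g in 0% and 0.228%. Igf1 was seen in 0.177% and 0.237% of neutrophil-like cells, against 0% (up to 0.378%) and 0.439% (0.011 to 2.42%) of photoreceptor-like cells, which is within the background. Unthinned, Arg1 was seen in 12.1% and 30.7% of neutrophil-like cells, Cxcr2 in 33.7% and 73.0%, and Ly6g in 2.93% and 30.8%.

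**Figure D3:**
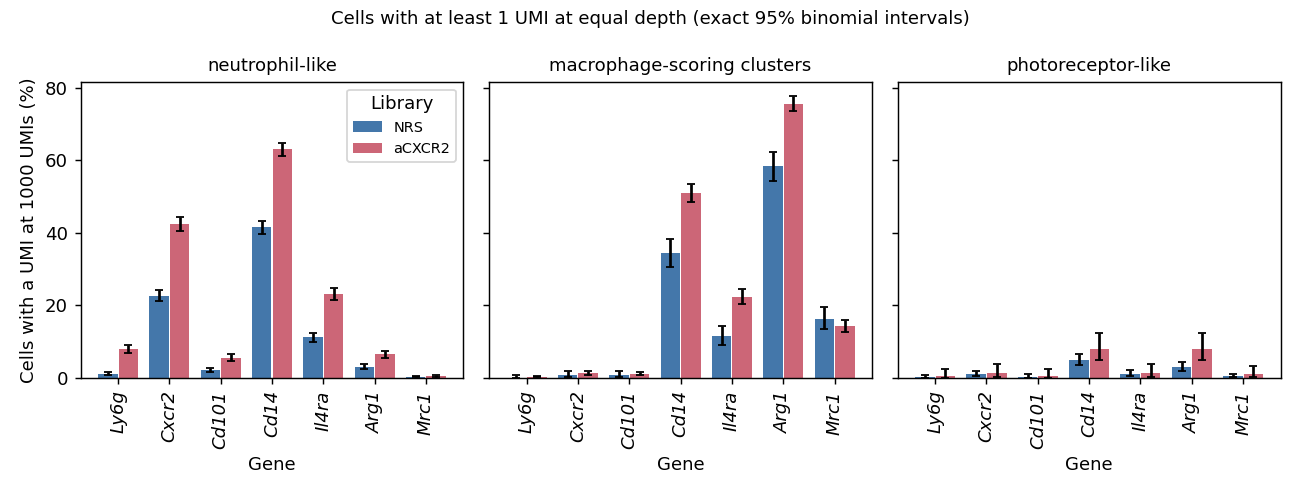
Percent of cells with at least 1 UMI after thinning to 1000 UMIs, for 7 genes in neutrophil-like, macrophage-scoring and photoreceptor-like cells of the NRS and aCXCR2 libraries, with exact 95% binomial intervals. Arg1 in neutrophil-like cells (3.01% and 6.40%) lies at the level in photoreceptor-like cells (2.90% and 7.89%), and Cxcr2 lies far above it.

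Per cell, the specific granule list took a median of 0.719% of UMIs in NRS (quartiles 0.277 and 1.77%) and 2.24% in aCXCR2 (1.23 and 3.47%). The mature surface list took 0.150% and 0.510%, the interferon-stimulated list 0.0333% and 0.171%, and the alternative activation list 0.322% and 0.369%. The proliferation list took 0.0426% and 0.0544%. The spread over cells is not an error of the library.

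Within single neutrophil-like clusters the median of the surface list lay near 0, with members on both sides. In the 6 clusters with at least 50 cells in each library (1, 2, 3, 6, 9 and 11), the mature surface median ran from -0.19 to 0.11. The specific granule median ran from -0.34 in cluster 3 to 1.34 in cluster 6, which held 55 NRS cells. In clusters 1, 2, 9 and 11 it was -0.31, 0.15, 0.033 and -0.00059, so only cluster 6 lay far above 0. These genes were not left out of the clustering, which had no correction for library, so medians near 0 do not show that the cells were alike. Heat shock medians ran from -0.67 to -0.22, with 3 of 8 members over 1.5-fold lower and 1 higher in cluster 1, 3 of 7 lower and 1 higher in cluster 6, and 5 of 9 lower and 0 higher in cluster 2.

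Over all kept cells, 170 of 3550 genes were at least 2-fold higher and 395 at least 2-fold lower in aCXCR2, and TMM factors gave 530 and 252. The largest ratios were those of Retnlg (log2 4.24), the chemokine genes Ccl5 (3.84) and Ppbp (3.73), Vcan (3.63) and BC100530 (3.58). The smallest were those of retina and lens genes, Vax2os (-5.12), Crybb2 (-5.02), Mlf1 (-4.34), Crym (-3.76) and Gnat1 (-3.74). Arg1 was 1303 CPM in NRS and 2537 CPM in aCXCR2 (log2 0.96), Mrc1 61.0 and 120 CPM (0.98), and Igf1 68.5 and 31.0 CPM (-1.14). All 7 MHC class II genes were over 1.5-fold higher (median 2.34). Within cluster 5, H2-Aa, H2-Ab1, H2-Eb1 and Cd74 summed to 24751 CPM in NRS (34 cells) and 11918 CPM in aCXCR2 (619 cells). In cluster 14 they summed to 12089 CPM (21 cells) and 12679 CPM (371 cells). The all-cell rise thus went with larger shares of these clusters, not with a higher level inside them.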

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

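The tests below were chosen after the patterns were seen, and the outcomes of 3 of them, Arg1-rich cells, free RNA of granule genes and cells matched on UMI count in doublings, were not known when their predictions were written.

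Rod photoreceptor markers were present in barcodes that the cell filter removed and that entered only the alternative with no cell filter. They made up 4.05% of those barcodes' UMIs in NRS and 1.02% in aCXCR2, against 1.004% and 0.087% of the UMIs of kept cells.

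Some list medians had opposite signs in neutrophil-like cells and in single macrophage-scoring clusters, with 1 library per group, and the difference was not tested. Proliferation genes had a median log2 ratio of 0.35 in cluster 7 and -1.90 in neutrophil-like cells. In cluster 12 interferon-stimulated genes were at -1.03 (0.58 in neutrophil-like cells), MHC class II genes at -0.39 (1.60) and hypoxia response genes at 1.36 (-0.39). Those of proliferation, interferon-stimulated and hypoxia genes turned with the summary, the scaling or the clusters counted, and the MHC class II sum in aCXCR2 neutrophil-like cells was 143 CPM beside 115 CPM in photoreceptor-like cells. In neutrophil-like cells proliferation genes were at 0.36 as a sum of UMIs, hypoxia genes at 0.28 and 0.30 with median of ratios and TMM factors, and interferon-stimulated genes at -0.027 without cluster 1, and in cluster 12 the interferon-stimulated sum was 1.04-fold.

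Arg1 CPM in neutrophil-like cells was higher in aCXCR2. Free RNA from macrophage-scoring cells could account for it, since the equal-depth share of 6.40% was no higher than in photoreceptor-like cells (7.89%). Arg1 in neutrophil-like cells was 1.92% of its CPM in macrophage-scoring clusters of aCXCR2, beside 2.26% for Mrc1, 2.09% for Apoe and 1.25% for C1qa. In aCXCR2, 8 of 2530 neutrophil-like cells, 0.316% (0.137 to 0.622%), had at least 3 Arg1 UMIs of 1000, against 50.1% of macrophage-scoring cells. This argues against a sizeable subset of the class with Arg1 at the level of macrophage-scoring cells. Cells with less Arg1 would mostly fall under 3 UMIs, so a subset at a lower level stays open. Expression below the background stays open, as do neutrophils that clustered elsewhere and expression in NRS, where Arg1 CPM was 31.8 in neutrophil-like and 18.5 in photoreceptor-like cells.

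In all cells, the mean log2 ratio of Arg1 and Mrc1 was 0.97, and the larger UMI share of macrophage-scoring clusters alone would give 1.01. That share went from 33.0% to 66.5%, a rise that came from the unnamed clusters 5 (1.17% and 21.3%), 12 (6.99% and 13.7%) and 14 (1.07% and 14.2%), while the named macrophage-like clusters went from 23.7% to 17.2%. Macrophage-scoring clusters held 94.2% of Arg1 and 97.9% of Mrc1 UMIs in NRS, and 98.5% and 98.7% in aCXCR2. The all-cell ratio is thus nearly the share ratio times the ratio within these clusters, and the 2 parts are not separate tests. Within these clusters as a sum the larger fold was 1.01, so the summed level was about the same in both libraries. The sum hides clusters that differ, with Arg1 at 514 and 3157 CPM in cluster 12 (log2 2.62) and at 2437 and 1771 CPM in cluster 17 (-0.46). Whether serum treatment or cell recovery set the share of these cells stays open, as each group was 1 library.

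Granule and surface genes were higher in aCXCR2 neutrophil-like cells. Cells matched on UMI count in doublings did not decide on depth by the bounds written beforehand, as the lowest medians were 0.44 and 0.095. A range of 4000 to 16000 UMIs was then taken, after its groups had been seen to have higher medians, so it is no separate test. Narrower matched groups in that range had medians of at least 1.13 for granule genes and 1.20 for surface genes, with no lower bound under 0.985. In those cells a difference thus remained at like depth. In shallower cells depth and a change in the cells cannot be told apart, as the medians were 0.81 (0.12 to 0.90) and 0.62 (0.12 to 0.87) at 1000 to 2000 UMIs and 0.44 (0.15 to 0.55) and 0.095 (-0.27 to 0.25) at 2000 to 4000 UMIs. Free RNA is argued against as the whole cause, because for the median of 18 members photoreceptor-like CPM was 10.8% of the gain. In 7 clusters made without these genes the surface list's median was at most 0.20, and granule medians ran from -0.41 to 1.24. No correction for library was made, and most of these clusters came mainly from 1 library. A change in all cells of a library could also set clusters apart, so these medians cannot tell cluster make-up from a change in the cells. The more mixed clusters, of 594 NRS and 317 aCXCR2 cells and of 319 and 504, had surface medians of 0.15 and -0.085 and granule medians of 0.36 and 0.67. The serum treatment stays open for both lists.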

How the results depend on the processing

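No paired analysis was possible because each group had 1 library, and for the same reason no library was left out. Counting every kept cell gives no share of neutrophil-like cells, so that alternative was not run for it. The alternatives that added or dropped clusters, removed the highest doublet scores used a prior of 10 CPM or took the share expected over all draws were chosen after seeing the data. Beyond the explanations examined above, causes were not tested. Depth limits genes such as Mrc1 and Igf1, which stood near 1 to 4 CPM in neutrophil-like cells.

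The neutrophil-like share (51.9% NRS, 53.3% aCXCR2) became 64.1% and 55.2% at resolution 0.5, 68.5% and 58.8% with the strict filter, 63.9% and 55.2% with doublets kept, 61.0% and 55.2% with libraries clustered separately, 63.7% and 55.2% with cluster 4 added, 30.9% and 51.8% without cluster 1, and 65.7% and 56.7% without the highest doublet scores. It was 48.8% of NRS at resolution 2, 50.5% of NRS with a prior of 10 CPM and 49.7% of aCXCR2 with no cell filter. Keeping doublets added 0 NRS and 4 aCXCR2 cells, so its NRS share moved through new clusters and names and not through added cells. The order of the libraries therefore turned with the cell filter, the clustering and the clusters counted.

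In neutrophil-like cells, genes at least 2-fold higher and lower (131 and 614) became 61 and 171 without cluster 1, 486 and 102 with median of ratios factors, 503 and 100 with TMM, 233 and 294 without the 20 most abundant genes, 235 and 1846 at a minimum of 10 CPM and 654 and 5362 with no minimum. Those lower were 325 at 100 CPM and 395 in all kept cells. In all cells (170 and 395) they became 593 and 244 with median of ratios factors, 530 and 252 with TMM, 334 and 1498 at 10 CPM and 953 and 5978 with no minimum. Those higher were 265 with no cell filter, and those lower were 217 with the strict filter and 179 at 100 CPM.

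Lists with a median above 0.3 (8) became 3 without cluster 1, 15 with median of ratios factors, 16 with TMM and 13 without the 20 most abundant genes. Lists below -0.3 (8) became 2 with median of ratios factors, 2 with TMM and 5 in all kept cells. Of 414 list values under alternatives, 23 turned sign, in 12 of 23 lists. Of lists with a main median beyond 0.3 either way, 10 values turned, for proliferation (0.073 in all kept cells, 0.36 as a sum of UMIs), classical activation (-0.072), trafficking (-0.14) and interferon-stimulated genes (-0.027) without cluster 1, interferon-stimulated genes in all kept cells (-0.60), and neurotrophic (0.13 and 0.15) and hypoxia genes (0.28 and 0.30) with median of ratios and TMM factors. Of the lists nearer 0, apoptosis (0.45, 0.47 and 0.076) and glycolysis genes (0.41, 0.43 and 0.032) turned with median of ratios factors, with TMM and without the 20 most abundant genes. Immediate early (-0.24), chemokine (-0.22), zymosan (-0.055) and matrix genes (-0.0011) turned without cluster 1, matrix (-0.31) and chemokine genes (-0.027) as a sum of UMIs, and chemokine genes (-0.048) with cells weighted equally.

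Of 1584 values of named genes, 27 turned sign, 11 of them in all kept cells and 4 each with TMM and median of ratios factors. Of genes at least 2-fold apart in the main result, 9 values turned. In all kept cells these were Stfa3 (-0.11), Ccl9 (1.04), Mki67 (0.57), Inhba (0.38), Ccl7 (0.042), Hsp90b1 (0.12) and Mmp14 (1.33). The others were Ifit3 (0.43) with libraries clustered separately and Chil3 (-9.40e-05) without the highest doublet scores.

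Thinning to 1000 UMIs moved the per-cell medians to 0.3% and 0.4% (alternative activation, NRS and aCXCR2), 0% and 0.2% (interferon-stimulated), 0.1% in NRS (mature surface) and 0% and 0% (proliferation). Of 24 shares of cells with a UMI, 18 moved beyond their interval at 500 UMIs, 18 at 2000 UMIs, 22 with no thinning and 1 when taken over all draws, Cd101 in NRS (2.06% to 2.91%).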

Other observations

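Macrophage-scoring clusters with at least 50 cells in each library differed between libraries in their own ways. Igf1, a growth factor gene, was lower in aCXCR2 in each of them, at 28.5 and 14.9 CPM in cluster 7 (log2 -0.94), 436 and 119 CPM in cluster 12 (-1.87) and 217 and 80.5 CPM in cluster 17 (-1.43). Apoe was also lower in each, at -0.42, -0.97 and -0.39. Ccl5 was higher in each, at 4.22, 1.03 and 1.30. It was also a leading gene of cluster 14, with 21 NRS and 371 aCXCR2 cells, and free RNA was not tested for it. These 3 genes were chosen after their values were seen, and no replicate supports them.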
